A study of Mus musculus with 2 samples.

How the data were processed

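Polyadenylated RNA longer than 200 nt was measured by strand-specific paired-end sequencing (101 nt reads) in 2 libraries of cortex from adult C57BL/6J mice of 8 weeks. Per the labels, the tissue is cortical plate, littermates of both sexes were pooled and external spike-in RNAs were added. The libraries are biological replicates 1 and 2 of 1 group, called adult cortex here. No second condition exists in the series, so no contrast between conditions was possible, and the comparisons describe the tissue and the difference between these 2 libraries.

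Per the file headers, the gene and transcript tables give expected counts, TPM and FPKM for each library, with posterior means and credible bounds of TPM. The authors made those tables on the mm10 assembly (GRCm38) with release 4 of the GENCODE mouse annotation. The deposited expected counts are fractional where reads fit several genes, and the deposited TPM values are scaled to one fixed total over all rows, control sequences included. The deposited transcript tables also give each isoform as a percent of its gene. The program and the level of its credible intervals are not stated in the files. The deposited gene and exon tables on the older mm9 assembly give RPKM in a pair of columns, with the Ensembl 65 annotation. The deposited junction table on mm9 gives counts of junction reads in a pair of columns. The deposited contig table on mm9 gives a signal level per contig, with an irreproducibility value. Which mm9 column belongs to which replicate is not stated, so mm9 columns were not assigned to replicates, and mm9 positions were not set beside mm10 positions. Assembled transcript models and the mm9 transcript table were not used here.

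Gene symbols, types and positions were taken from release 21 of the GENCODE mouse annotation on GRCm38 by unversioned Ensembl identifier, which gave a symbol to 98.0% of the 43346 gene rows; the rest held 0.152% of gene counts. Totals were 91875460 expected counts in replicate 1 and 92939474 in replicate 2, of which 88327121 and 88643335 were on gene rows. Scaling used TMM effective library sizes from edgeR 4.0.16, which also gave the common biological coefficient of variation from an intercept-only design. R was version 4.3.3.

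The 2 libraries were compared gene by gene with an exact two-sided binomial test on rounded expected counts, for genes with at least 10 counts over both libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 ratios added 0.5 counts to each library. Ratio intervals are 95% Clopper-Pearson intervals. Intervals and count limits (3 counts for a count of 0) cover counting error only, since reads without molecular identifiers are not independent molecules. The p-values compare these 2 libraries and no conditions.

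The gene lists (16 of cell classes, 10 of regions or stages, 10 of cell states or gene families), the 17 gene pairs, the isoform genes, the tests and the rule for naming genes were fixed before the data were examined. The level of a list is its median log2(TPM + 1) in each library, placed among 10000 random lists of the same size from genes with at least 1 count. The difference of a list is the median log2 ratio of replicate 2 to replicate 1 over members with at least 10 counts. It was placed among 10000 random lists matched on expression in 20 bins, and it was called outside when it left their central 95% range. Gene pairs were compared as log2 TPM ratios, and isoforms as shares of gene TPM for genes with at least 10 TPM. Inclusion of an internal exon used the mean of the junction reads at its ends, as a percent of that mean plus the skipping reads. At least 20 such informative reads were needed in each mm9 column. Reads at exon ends came only from junctions with the A flag set, a flag taken as annotated whose meaning is not stated. Skipping reads came from any junction, flagged or not, between the outer sites of those junctions. Other skipping was not counted. Exons of 3 to 27 nt (microexons) were compared with longer internal exons of the same genes by the share with 10% to 90% inclusion, in a two-sided permutation test with 100000 resamples. Shares of exons have 95% Wilson intervals. Contigs were sorted by overlap of at least 1 base with genes of the same mm9 annotation, using bedtools 2.31.1. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

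Genes were named by rule: the 10 with the highest mean TPM, mitochondrially encoded genes apart; for each list the 3 most abundant members and the least abundant; the 10 with the largest library ratio in each direction among genes past the threshold with at least 100 counts in the higher library; each gene pair; isoform genes whose leading transcript held under 60% or differed between libraries; the 10 with the largest difference between annotations in each direction; the microexons of intermediate inclusion with most reads; and the longest and strongest contigs outside genes. Other list members printed here were chosen after their values were seen, and of the genes the rule names, those not printed are covered by counts.

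The gene test was tested on simulated Poisson counts for 19801 genes: it recovered 100% of 2-fold and 65.0% of 1.2-fold changes, with 2.37% false calls. The changed genes were drawn from those with at least 100 counts over both libraries. The real libraries differed by more than Poisson noise (spread of z 2.14), so these rates do not carry over to the calls below. The list test put 2.67% of 300 unchanged lists outside the range and found 100% of 100 shifted ones. Those were shifted by log2 0.5 among well covered genes, so smaller shifts and genes with few counts were not covered. Simulated genes varied independently, so this does not cover lists whose members move together. The inclusion measure called all 100 short exons simulated at intermediate inclusion. Alternatives tried were DESeq2 1.42.0 median-ratio size factors, plain totals, other count filters, fold limits, inflated noise, other units, pseudocounts, list members and random lists, each replicate left out, the mm9 quantification, and other limits for reads, inclusion, exon size and contig overlap.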

Results

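Polyadenylated RNA from the cortex of adult mice was sequenced in 2 libraries, biological replicates 1 and 2 of the only group. Total depth was 91875460 expected counts in replicate 1 and 92939474 in replicate 2. At least 1 TPM was reached by 14553 genes in replicate 1 and 14359 in replicate 2, of which 13091 and 13000 are protein-coding. Levels below are mean TPM ± SD over both libraries (n = 2), and gene positions are on mm10 (GRCm38).

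The most abundant nuclear protein-coding RNAs were Fth1, the heavy chain of the iron store ferritin, at 3143 ± 69.7 TPM, Cst3, a secreted protease inhibitor, at 2695 ± 27.1, and the glycolytic enzyme gene Gapdh at 2355 ± 105. Apoe, which encodes the main lipid carrier made by astrocytes, followed at 2290 ± 70.8, then Rplp1 at 2085 ± 147 and the myelin gene Mbp at 2017 ± 287. Eef1a1, Ubb, Ckb and Lars2 lay between 1603 and 1732 TPM. Lars2 had an SD of 895, since it was 2.57-fold (2.56 to 2.59) higher in replicate 2, at 970 and 2236 TPM. What its reads represent was not checked, so its place among messenger RNAs is uncertain. Mitochondrially encoded RNAs took 9.03% of gene counts in replicate 1 and 9.30% in replicate 2. By TPM they were led by mt-Atp8, mt-Co1 and mt-Co2, while mt-Ty, a transfer RNA gene, was listed at 0. They took 32.6% and 34.8% of TPM, in part because mt-Atp8, a subunit of ATP synthase, was divided by an effective length of only 12.6 and 10.4 nt. That gene held 19.0% and 21.9% of TPM from 0.184% and 0.191% of gene counts. The 10 highest nuclear rows of any type were not typical messenger RNAs. They were Gm42418, at 12240 ± 5871 TPM, the 7S RNA genes Rn7s1, Rn7s2 and Rn7sk, and 6 pseudogenes on chromosome 1 that copy mitochondrial sequence, from Gm29216 (24615706 to 24616197) to Gm28438, whose levels are uncertain because at least 96.7% of the read-length windows of each also occurred in mitochondrial genes. Spike-in RNAs took 2.99% and 3.22% of counts, and the 70 with at least 10 counts in both libraries had a Pearson r of 0.999 and a Spearman rho of 0.998 across RNAs, which are not independent replicates.

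The first comparison asked which cell classes gave RNA to the tissue. Genes of neurons in general had the highest median of the 16 classes, log2(TPM + 1) of 7.77 ± 0.09, with Snap25 of the vesicle fusion machinery at 1530 ± 91.8 TPM, the vesicle protein gene Syp at 585 ± 53.1 and Syt1 at 401 ± 44.9, down to Nefh at 17.9 ± 0.622. Oligodendrocyte genes followed at 7.33 ± 0.18, with Mbp and with Mobp at 518 ± 72.0. Excitatory neuron genes stood at 6.26 ± 0.18, with Nrgn at 1322 ± 120, Camk2a at 884 ± 102 and the vesicular glutamate transporter gene Slc17a7 at 525 ± 65.8. Astrocyte genes stood at 5.83 ± 0.18, with Aldoc at 850 ± 42.4 and the glutamate transporter gene Slc1a2 at 403 ± 21.9. Red blood cell genes (5.39 ± 0.33, or 3.27 without the most abundant member), microglial genes (5.04 ± 0.14) and genes of interneuron subclasses (4.82 ± 0.06) were also above the 95% range of random lists in both libraries, 7 of the 16 classes in all, or 6 without the most abundant member of each list and 5 with random lists from genes with at least 1 TPM. Hba-a2 reached 237 ± 35.5 TPM, and the neuropeptide genes Cck and Sst 810 ± 120 and 440 ± 18.5.

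The other 9 classes did not leave that range in both libraries. Oligodendrocyte precursor genes (4.33 ± 0.04), inhibitory neuron genes (3.92 ± 0.06), endothelial genes (3.83 ± 0.07), mural genes (3.04 ± 0.01) and meningeal fibroblast genes (2.54 ± 0.01) stood highest among them. Single members were abundant all the same: Gad1, an enzyme of GABA synthesis, reached 171 ± 0.0283 TPM, Olig1 112 ± 2.21, Ly6c1 of endothelium 110 ± 0.0424 and Vtn of pericytes 88.7 ± 2.01. Ptgds of the meningeal list reached 1214 ± 22.7 TPM, against a median of 4.91 for that list, so this gene does not speak for the list. Ependymal (1.71 ± 0.37), leukocyte (0.95 ± 0.17), choroid plexus (0.53 ± 0.06) and skeletal muscle genes (0.19 ± 0.12) stood lowest, with Cd3e of T cells at 0.0250 ± 0.0212 TPM, although Ttr of the choroid plexus reached 17.1 ± 3.23.

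**Figure D1:**
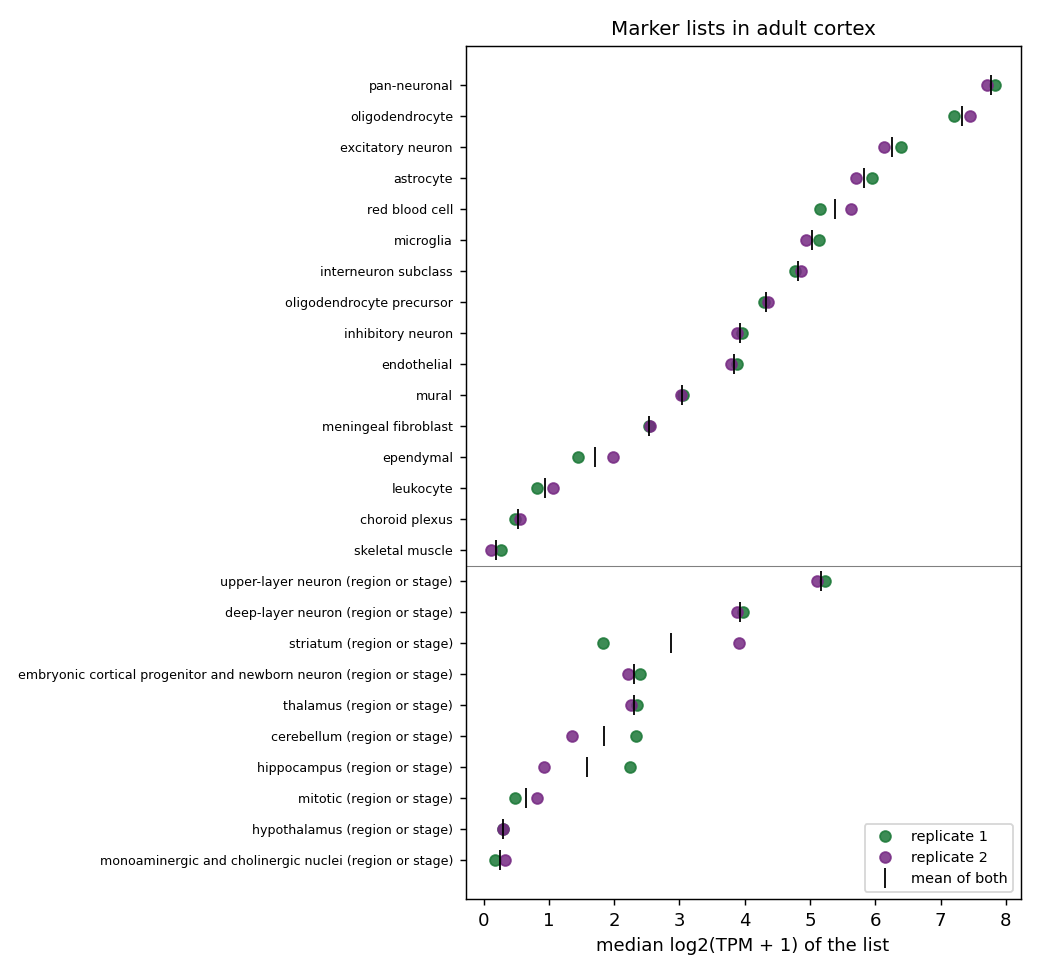
Median log2(TPM + 1) of each cell-class list (top) and each region or stage list (bottom) in replicate 1 (green) and replicate 2 (purple), with the mean of both as a bar. The pan-neuronal list is highest at 7.77, and the libraries stand apart on the striatal list at 1.82 and 3.91 and on the hippocampal list at 2.24 and 0.93.

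The next comparison asked which cortical layers, other brain regions and stages left their markers. Upper-layer neuron genes were the only 1 of 10 such lists above the range of random lists in both libraries, at 5.17 ± 0.08, with Lhx2 at 43.2 ± 3.44 TPM, Rasgrf2 at 41.8 ± 2.84 and Cux2 at 37.5 ± 0.233. That call was lost, leaving 0 lists, when the most abundant member was left out or when random lists were drawn from genes with at least 1 TPM. Deep-layer genes stood at 3.93 ± 0.06, with Crym at 36.0 ± 4.62, the subplate gene Ccn2 at 20.6 ± 1.14 and Fezf2, a regulator of projections below the cortex, at 18.4 ± 3.32. Genes of embryonic progenitors and newborn neurons stood at 2.31 ± 0.13: Vim, also present in glia, reached 48.7 ± 2.08, while Eomes of intermediate progenitors stood at 0.0600 ± 0.0566. Thalamic genes stood at 2.31 ± 0.06 and cerebellar genes at 1.85 ± 0.69. Mitotic (0.65 ± 0.23), hypothalamic (0.30 ± 0.00386) and monoaminergic and cholinergic genes (0.26 ± 0.11) stood lowest, with the hypothalamic gene Sim1 listed at 0. The striatal list stood at 1.82 in replicate 1 and 3.91 in replicate 2, and the hippocampal list at 2.24 and 0.93.

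Because no second condition exists, the only contrast between libraries is replicate 2 against replicate 1. Its largest feature was regional. All 11 tested striatal genes were higher in replicate 2, by a median of 4.37-fold (log2 2.13, SD over genes 0.90), among them Drd2, the dopamine D2 receptor gene (ENSMUSG00000032259, chromosome 9, 49340627 to 49408177), at 17.3-fold (95% interval 13.7 to 22.3), the adenosine receptor gene Adora2a at 10.8-fold (9.43 to 12.4) and the enkephalin gene Penk at 4.37-fold (4.15 to 4.61). Ppp1r1b, a relay of dopamine signalling that cortex also expresses, was higher by 2.63-fold (2.56 to 2.70). All 6 hippocampal genes were lower in replicate 2, by a median log2 of −1.95 (SD over genes 1.45): Dsp, a marker of dentate granule cells (ENSMUSG00000054889, chromosome 13, 38151294 to 38198577), was 27-fold (18.2 to 43.8) higher in replicate 1, C1ql2 4.44-fold (3.77 to 5.28), Fibcd1 2.29-fold (2.11 to 2.48) and Prox1 1.42-fold (1.33 to 1.52). The 11 striatal and 6 hippocampal genes passed the exact binomial test after Benjamini-Hochberg adjustment over all genes tested, and the same counts passed when adjusted over the list alone. Cortical upper-layer genes had 0 of 9 members past the threshold, over all genes or adjusted over the list alone, and a median log2 of 0.037 (−0.11 on TPM ratios).

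**Figure D2:**
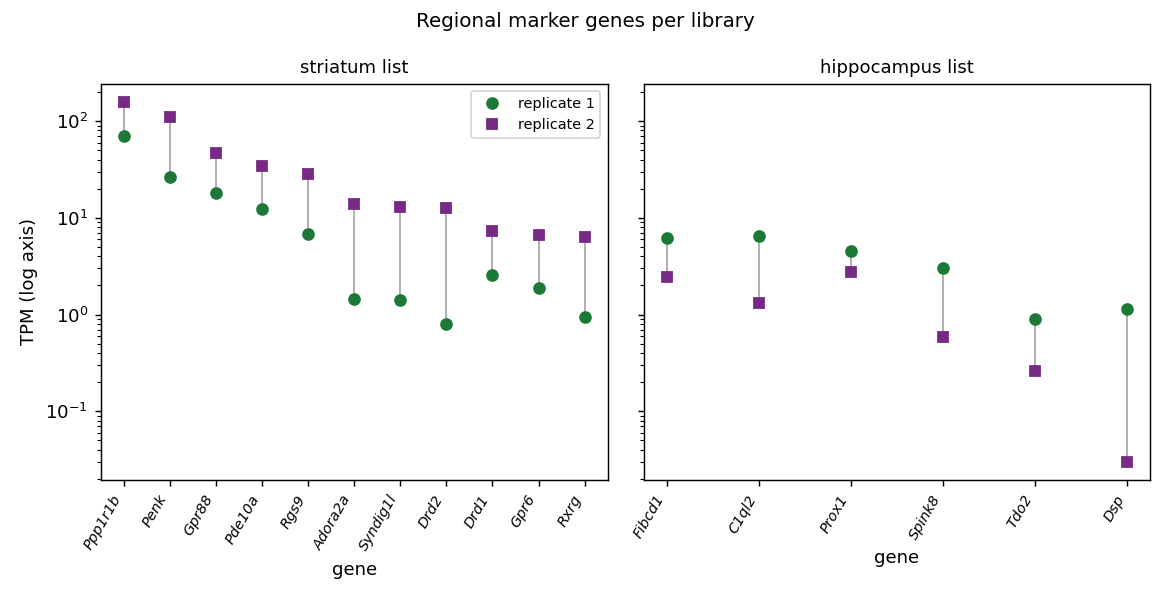
TPM on a log axis of each striatal gene (left) and each hippocampal gene (right) in replicate 1 (green circles) and replicate 2 (purple squares), joined by a line per gene. All 11 striatal genes are higher in replicate 2 and all 6 hippocampal genes are higher in replicate 1.

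Other groups moved by less. All 15 immediate early genes, which neurons switch on with activity, were higher in replicate 2 (15 when adjusted over the list alone), by a median log2 of 0.50: Arc by 1.77-fold (1.73 to 1.80), Egr1 by 1.42-fold (1.39 to 1.45) and Egr2 by 2.64-fold (2.33 to 3.01). All 11 oligodendrocyte genes were higher too (11 adjusted over the list alone), by a median log2 of 0.41, Mbp by 1.34-fold (1.34 to 1.35) and Mag by 1.40-fold (1.38 to 1.43). Ependymal genes had a median log2 of 0.92, with 6 of 6 past the threshold (6 adjusted over the list alone) and Tmem212 at 3.58-fold (2.11 to 6.68). Choroid plexus genes had 0.68, with 5 higher and 1 lower of 10 (6 and 1 adjusted over the list alone): Ttr was higher by 1.45-fold (1.34 to 1.58) and Kl lower. Mitotic genes had 0.82, with 5 of 8 higher (5 adjusted over the list alone), as Mki67 of dividing cells by 2.20-fold (1.74 to 2.81), at only 0.235 ± 0.106 TPM. Red blood cell genes had 0.51, with 5 of 6 higher (5 adjusted over the list alone), as Hbb-bs by 1.37-fold (1.33 to 1.41). Monoaminergic and cholinergic genes had 0.86, with 2 of 6 higher (2 adjusted over the list alone): Chat and Slc18a3, which make and load acetylcholine, at 6.22-fold (4.13 to 10.1) and 2.28-fold (1.44 to 3.77). Interferon response genes had 0.23, with 5 of 9 higher (7 adjusted over the list alone), as Ifit1 by 1.59-fold (1.38 to 1.85), but lay inside the random range on TPM ratios (0.021). Meningeal genes had 0.21, with 6 of 10 higher (8 adjusted over the list alone), as Apod by 1.35-fold (1.31 to 1.39).

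On the lower side, glucocorticoid response genes had a median log2 of −0.15, with 4 lower and 1 higher of 8 (4 and 2 adjusted over the list alone): Zbtb16 was 1.53-fold (1.47 to 1.60) and Fkbp5 1.32-fold (1.24 to 1.41) higher in replicate 1. This list also lay inside the random range on TPM ratios (−0.26). Cerebellar genes had −0.26, with 4 lower and 2 higher of 10 (4 and 2 adjusted over the list alone); Pcp2 of Purkinje cells had 66 counts in replicate 1 and 2 in replicate 2, a ratio of 26.1 (8.61 to 273). Skeletal muscle genes had −0.85 over 4 genes, with 2 lower (2 adjusted over the list alone), Acta1 and Ckm (21 and 0 counts); their list was inside the random range when genes with at least 1 or at least 50 counts were used. Small positive medians outside the random range, which turned negative on plain TPM ratios, were those of precursor genes of oligodendrocytes (0.16), thalamic (0.13), inhibitory neuron (0.12), interneuron subclass (0.090), mitochondrially encoded (0.078), astrocyte (0.057) and circadian genes (0.056). In that order, 4, 2, 5, 7, 9, 8 and 7 members were higher past the threshold (4, 2, 5, 7, 9, 9 and 8 adjusted over the list alone), and 2, 0, 0, 1, 4, 2 and 1 were lower (2, 0, 0, 2, 4, 3 and 2 adjusted over the list alone). With means in place of medians, the precursor, thalamic, inhibitory, astrocyte and circadian lists lay inside the random range, and the thalamic list did so with genes of at least 1 or at least 50 counts. TPM ratios shift the median of all genes by −0.16 (log2). In all, 21 of the 35 lists left the central 95% range of random lists. If members varied independently 1.75 would, but markers of a cell class or state can move together. That number is therefore no measure of chance for these lists.

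**Figure D3:**
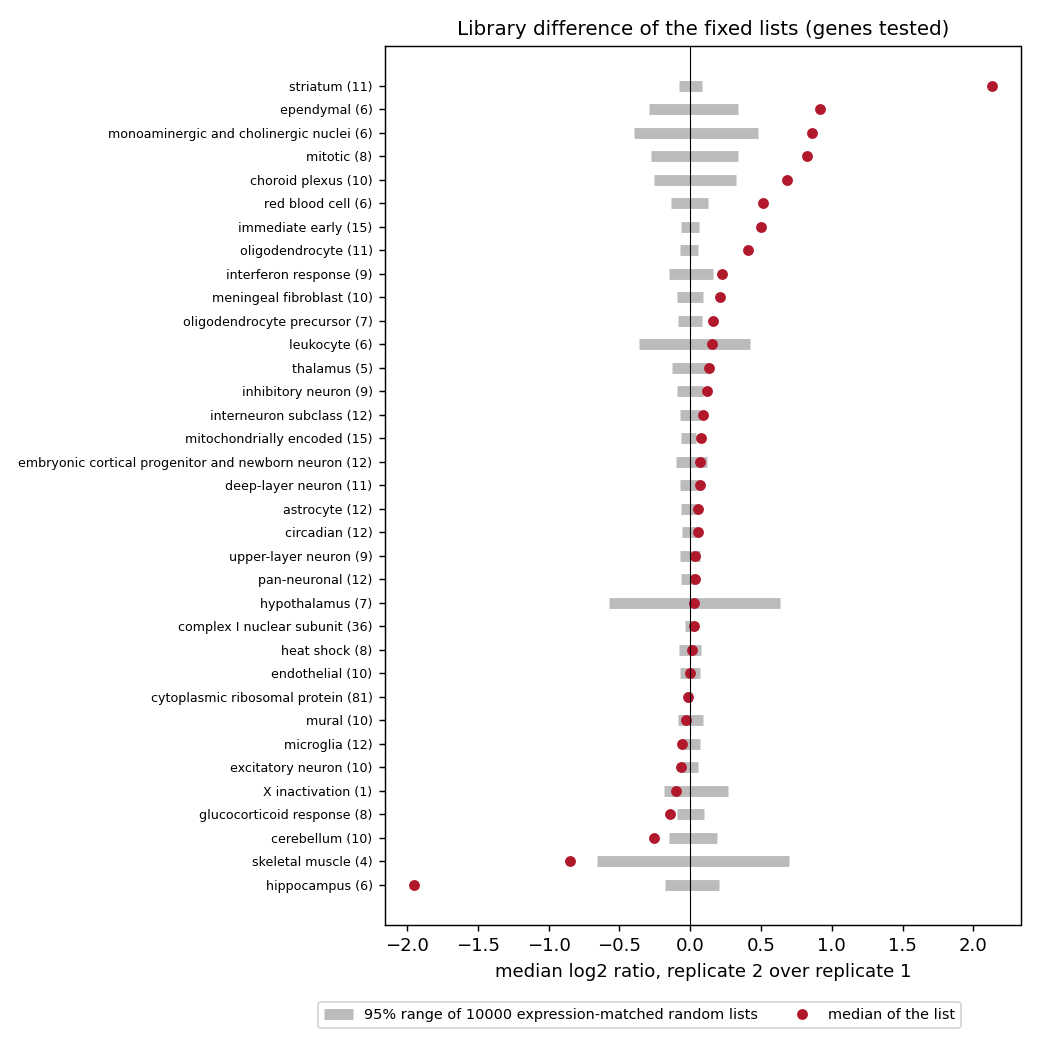
Median log2 ratio of replicate 2 to replicate 1 for each fixed list (red points, genes tested in brackets), with the 95% range of 10000 expression-matched random lists in grey. The striatal list (2.13) and the hippocampal list (−1.95) lie farthest from the grey ranges; on plain TPM ratios, 7 positive medians outside their grey ranges and 8 inside turned negative.

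Lists inside the random range were the pan-neuronal (median log2 0.036; 7 higher and 3 lower of 12), excitatory neuron (−0.063; 1 and 6 of 10), microglial (−0.057; 0 and 5 of 12), endothelial (−0.00382; 1 and 2 of 10), mural (−0.028; 2 and 2 of 10), leukocyte (0.15; 0 and 0 of 6), deep-layer (0.070; 5 and 2 of 11), hypothalamic (0.028; 1 and 0 of 7) and embryonic lists (0.072 with a mean of −0.047; 3 and 0 of 12). Adjusted over the list alone, those counts were in the same order 7 and 3, 1 and 7, 0 and 5, 1 and 2, 2 and 2, 0 and 0, 5 and 3, 1 and 0, and 5 and 0. Of these lists, the pan-neuronal (−0.12), leukocyte (−0.00192), deep-layer (−0.088), hypothalamic (−0.11) and embryonic (−0.037) medians turned negative on TPM ratios. The heat shock list (0.012 with a mean of −0.040; 4 and 2 of 8, 4 and 3 adjusted over the list alone), led by Hspa8 at 1099 ± 8.89 TPM, also stayed inside and had −0.12 on TPM ratios. So did cytoplasmic ribosomal protein genes (−0.017; 19 and 26 of 81, 21 and 29 adjusted over the list alone), led by Rps21 at 1299 ± 115 TPM, and nuclear complex I genes (0.025; 10 and 4 of 36, 10 and 4 adjusted over the list alone), led by Ndufa4 at 641 ± 9.24 TPM. The excitatory list fell outside when means were used (−0.099) and the complex I list on TPM ratios, where its median turned negative (−0.12). Xist, the RNA of X inactivation, was at 89.6 ± 14.3 TPM and lower in replicate 2 (log2 −0.10, 1 of 1 past the threshold, 1 adjusted over the list alone). Of the Y-linked genes, Ddx3y, Uty and Kdm5d had 0 counts in both libraries and Eif2s3y had 1 and 0, too few to test. A count of 0 allows 3 counts, which for Uty was at most 0.110% of the count of the X-linked Kdm6a.

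Outside the lists, the largest ratios toward replicate 2 included the forebrain regulator gene Six3 (4 and 210 counts, 47.7-fold, 20.6 to 198) with its antisense gene Six3os1 (1 and 128 counts), Serpina9 (5 and 264 counts) and Ido1, an enzyme of tryptophan breakdown (15 and 162 counts), beside Drd2, Adora2a and Syndig1l. Toward replicate 1 they included Capn11, Lhx9, Slc9a4, Lct, Ndst4 and Lefty1, each between 4.09-fold (3.06 to 5.63, Lefty1) and 9.83-fold (6.20 to 17.4, Capn11), beside Dsp and C1ql2. Rdh9 (5 and 123 counts) and Rdh16f1 (114 and 2.52 counts) overlap on chromosome 10 and went in opposite directions, as did 3 genes without a symbol, each with 0 counts in one of the libraries, so these differences are uncertain. In all, 5611 of 19829 genes (28.3%) passed the exact binomial test after Benjamini-Hochberg adjustment, 2873 higher and 2738 lower in replicate 2, and 1132 passed with noise inflated to the observed spread. The share higher was 51.2% with TMM scaling and 33.3% of 6106 genes with plain totals. Both libraries were close on the whole: Pearson r across genes was 0.996, the median absolute log2 ratio was 0.11, 86.1% of the 15721 genes with at least 100 counts were within 1.2-fold, and the biological coefficient of variation was 0.0905. At this depth small differences pass the test: 825 genes also differed by 1.5-fold and 472 by 2-fold, of which 307 were higher and 165 lower in replicate 2.

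The 17 pairs of related genes compared forms typical of the adult brain or of a cell type with their relatives, as mean log2 TPM ratio ± SD. In 14 pairs the first gene was higher in both libraries. The neuronal Snap25 exceeded its widespread relative Snap23 by 7.25 ± 0.02, and Slc17a7 exceeded Slc17a6, the glutamate transporter gene typical of deeper brain, by 6.75 ± 0.23. The chloride exporter gene Slc12a5 exceeded the importer gene Slc12a2 by 3.47 ± 0.18, Gad1 exceeded Gad2 by 3.21 ± 0.02 (2.5 on mm9 and 1.56 without division by length), Dlg4 exceeded Dlg3 by 3.08 ± 0.06 and the sodium channel gene Scn1a exceeded Scn3a by 2.13 ± 0.02. Camk2a over Camk2b (1.70 ± 0.03), Ldhb over Ldha (1.52 ± 0.11), Gria2 over Gria1 (1.14 ± 0.10), Mapt over Map1b (1.09 ± 0.07), Slc1a2 over Slc1a3 (1.05 ± 0.02) and Gria1 over Gria4 (0.93 ± 0.15) were among the others. Pairs with the first gene lower included Grin2a over Grin2b, subunits of the NMDA receptor (−1.37 ± 0.05), and Aldoc over Aldoa (−0.51 ± 0.09). All 17 ratios exceeded the SD between libraries, but Mapt over Map1b turned negative without division by length (−0.29) and Aldoc over Aldoa positive on mm9 (0.094). Without division by length Grin2a over Grin2b (−3.56), Slc1a2 over Slc1a3 (2.56) and Slc17a7 over Slc17a6 (6.16) also moved, as did Snap25 over Snap23 on mm9 (6.65).

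Isoform shares asked which transcripts genes with known neuronal isoforms use. Of 37 such genes, 36 had at least 10 TPM, and in 14 the leading transcript held under 60% of TPM. The AMPA receptor gene Gria2 was led at 39.9% ± 1.57 by a protein-coding transcript of 4026 nt, ahead of one of 10371 nt at 26.6% ± 0.755. Grin1, the obligatory NMDA receptor subunit, was spread over 14 transcripts with 29.2% ± 0.443 in the first, and the dendritic gene Map2 over 24 with 26.5% ± 0.880. The leading transcript also held under 60% in Homer1 (31.7% ± 0.270), Dnm1 (30.9% ± 1.86), Ank2 (31.7% ± 1.68), Nrxn3 (51.4% ± 3.99), Tpm1 (40.5% ± 0.0256), Ncam1 (43.0% ± 2.21) and Cacna1a (44.2% ± 2.03). In Ank3 (21.8% ± 1.30) the leading transcript is a fragment of 534 nt, and in Agrn (52.7% ± 0.176) it retains an intron. The second transcript retains an intron in Ank2 (23.9% ± 0.133) and Nrxn3 (9.93% ± 1.00) and is a short processed one in Cacna1a (549 nt, 33.7% ± 1.54) and Dnm1 (810 nt, 23.1% ± 1.80), so the shares of these genes rest in part on incomplete models. Over 6023 genes with several transcripts, the leading one held a median of 66.0% ± 0.467, and it held under 60% in both libraries in 40.0% of genes.

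The older mm9 gene table was set against the newer tables to ask which levels depend on annotation and pipeline. As the TPM equivalent, mm9 RPKM was multiplied by 7.55, the median ratio of TPM to RPKM among genes with at least 10 TPM. That fixes the typical difference by construction. Differences were taken after adding 1 to both values. Of 79 cytoplasmic ribosomal protein genes with 10 TPM or its equivalent, 47 were more than 4-fold higher in the newer tables and 4 more than 4-fold lower (median log2 2.41, SD over genes 2.34): Rps12 stood at 838 ± 29.0 TPM against an equivalent of 4.08, Rpl38 at 943 ± 55.5 against 9.63 and Rps29 at 840 ± 36.3 against 17.8. Of 423 processed pseudogenes 373 were more than 4-fold lower (median log2 −3.49, SD over genes 1.68), as Gm9701, at 0 against 338, and Gm13394, at 1.62 ± 0.467 against 553. Both groups were chosen after the values were seen. Also lower were the small RNA genes Rny1 and Rny3, both listed at 0, and Gm24447 (0.715 against 1322). The pseudogene Gm7336 went the other way, at 181 ± 1.24 against 0.00833. The 37 mitochondrially encoded genes were listed at 0 on mm9. Across 33031 genes matched by identifier Pearson r was 0.959 and Spearman rho 0.962, and 588 of 8825 genes with 10 TPM or its equivalent (6.66%) differed more than 4-fold. Genes are not independent replicates, and r was 0.872 among genes with at least 1 in either table.

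Junction reads on mm9 asked how often microexons, which neurons are known to splice in, were skipped. Among the best covered microexons of intermediate inclusion, a 21 nt exon of the clathrin heavy chain gene Cltc (chromosome 11, 86514563 to 86514583) was included at 25.5% ± 0.0255, and 3 exons of the kinesin gene Kif1a at 35.3% ± 1.45, 24.2% ± 2.39 and 69.9% ± 4.46 (SD, n = 2 mm9 columns). The first 2 of these Kif1a exons had the same number of skipping reads, 2343, so their values are not independent. Sh3glb2 (89.3% ± 0.944), Dctn1 (87.6% ± 2.09), Picalm (71.1% ± 3.35), Nckap1 (71.4% ± 1.36), Ewsr1 (44.0% ± 0.963) and Mapk8ip3 (15.3% ± 1.01) followed. Most microexons were included: of 719 in 606 genes, the median inclusion was 99.0%, with 475 above 90% and 50 below 10%. At 10% to 90% inclusion were 194 microexons (27%, Wilson interval 23.9 to 30.3), against 362 of 10462 longer exons of the same genes (3.46%, 3.13 to 3.83). Some of these calls rest on uneven junctions, as in Arhgap21 with 322 and 1 reads at the ends of its exon. Overlapping exons, such as those of 12 and 15 nt in Macf1, were counted separately. The difference of 23.5 percentage points had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. Size labels were permuted over all exons together, without keeping genes apart, and exons are not independent replicates. The share was 47.3% (37.3 to 57.4) at 3 to 15 nt and was lower with each longer class, down to 1.95% (1.81 to 2.10) over 150 nt. Of the microexons at intermediate inclusion 87.1% had a length divisible by 3, against 58.9% of those above 90% (Fisher's exact test, two-sided, p = 1.79e-13), a comparison chosen after the inclusion values were seen. For longer exons of the same genes the shares were 73.8% and 41.6% (Fisher's exact test, two-sided, p = 6.39e-34), a test also chosen afterwards.

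**Figure D4:**
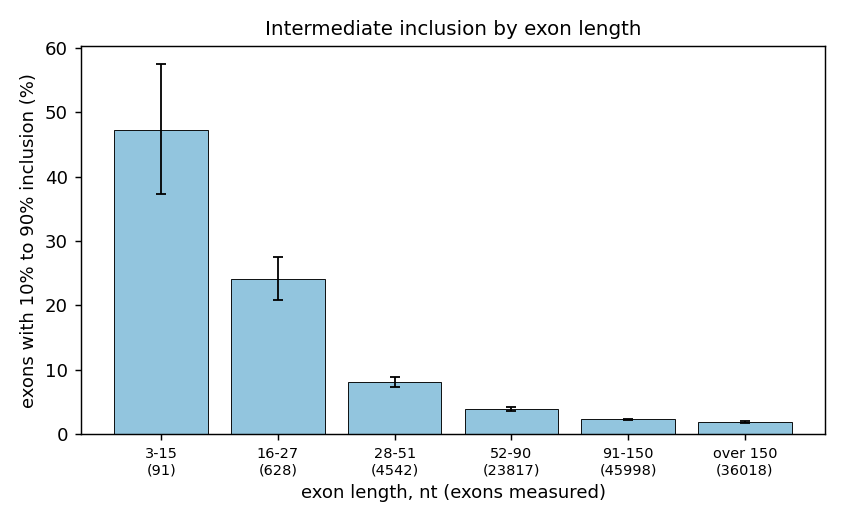
Percent of measured internal exons with 10% to 90% inclusion by exon length on mm9, with 95% Wilson intervals as bars and the number of exons in brackets. The share runs from 47.3% at 3 to 15 nt to 1.95% over 150 nt.

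Contigs of transcribed sequence on mm9 asked where RNA came from relative to annotated genes. The longest contig outside genes spanned 131403 nt on chromosome 14 (24677212 to 24808614, minus strand), 54686 nt from the potassium channel gene Kcnma1 on the same strand. The next spanned 87899 nt on chromosome 10 (109548233 to 109636131), 110958 nt from Nav3. The strongest outside genes was a 611 nt contig on chromosome 3 (5860313 to 5860923). Of 862041 contigs, 5 were mitochondrial and left out. Contigs outside genes made up 33.9% of the rest (Wilson interval 33.8 to 34.0; 22.1% at irreproducibility of at most 0.1) and 15.5% of their length but 5.38% of their signal. Contigs touching exons made up 14.0% of contigs, 37.3% of length and 83% of signal, intronic ones 42.4%, 43.2% and 8.44%, and antisense ones 9.68%, 3.93% and 3.21%.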

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

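Reads of phiX, the bacteriophage DNA used as a sequencing control, stood outside the main measurement and far above the 3 counts that a count of 0 allows. They numbered 800048 expected counts in replicate 1 (0.871% of the total) and 1299656 in replicate 2 (1.40%).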

How the results depend on the processing

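TPM rescaled without mitochondrially encoded and spike-in transcripts was chosen as an alternative for list levels after seeing the data. Of 198 list differences under alternatives, 165 kept their direction and their side of the random range, 11 lost the call, 1 gained it and 21 reversed. With TPM ratios 15 reversed, 7 of them from lists first called outside that range: inhibitory neuron −0.043, interneuron subclass −0.068, astrocyte −0.11, oligodendrocyte precursor −0.00333, thalamus −0.11, circadian −0.099 and mitochondrially encoded −0.075. The other 8 were first inside it: pan-neuronal −0.12, leukocyte −0.00192, upper-layer −0.11, deep-layer −0.088, hypothalamus −0.11, embryonic −0.037, heat shock −0.12 and complex I −0.12. With plain totals hypothalamus (−0.00516), heat shock (−0.021) and complex I (−0.00864) reversed, with means embryonic (−0.047) and heat shock (−0.040), and with at least 50 counts hypothalamus (−0.11). TPM ratios shift the median of all genes downward, as the report states. Of 102 gene pair ratios, 76 stayed within the SD between libraries, 24 moved beyond it and 2 reversed: Mapt over Map1b without division by length (−0.29), which that division explains, and Aldoc over Aldoa on mm9 (0.094); the cause of the latter was not tested. Of 259 list levels, 140 stayed within that SD and 119 moved.

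Of 78 summary values, 67 held. Genes called numbered 825 with a 1.5-fold and 472 with a 2-fold limit, by construction, and 1132 with noise inflated to the observed spread. Regional lists above random ones numbered 0 without the most abundant member and 0 with random lists of at least 1 TPM. Genes detected at 10 TPM averaged 8186.5, by construction. Across annotations r was 0.966 with pseudocounts of 0.1 and 0.01, and 0.872 for genes with at least 1 in either table. Contigs outside genes were 34.6% when at least 50% of the contig had to overlap and 22.1% at irreproducibility of at most 0.1. For the values not put down to construction the cause was not tested. With each replicate left out, genes detected ranged from 14359 to 14553, spike-ins from 2.99% to 3.22%, and cell classes above random lists stayed at 7, regional lists at 1, pairs at 14 and isoform genes at 14. Depth limits genes near 10 counts, such as Slc6a3.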

Other observations

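Among the tests below, those of scaling, of another brain region, of a missing Y chromosome, of depth at Y-linked genes and of longer RNAs were chosen after the result was seen, as was the margin (the spread of matched random lists, or of members for short genes) by which a list had to pass its limit.

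Single members of other lists also differed between the libraries. Tac1, the substance P gene that striatal neurons of the direct pathway also express, was 2.65-fold (2.41 to 2.91) higher in replicate 2, and Nr4a2 2.04-fold (1.90 to 2.19). The hypothalamic and basal forebrain regulator gene Nkx2-1 had 3 counts in replicate 1 and 46 in replicate 2, a ratio of 13.5 (5.03 to 78.6). Among excitatory neuron genes, Neurod6 was 1.34-fold (1.28 to 1.39) higher in replicate 1. These genes were named after their values were seen.

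Striatal genes were higher in replicate 2 and hippocampal genes in replicate 1. The lowest striatal median over the scalings tried was 2.05, but these moved the median of all genes too little (−0.16 at most) to decide. Scaling was argued against because it moves all genes alike, while the striatal median was 2.13 and the hippocampal −1.95. A library from another region as a whole was argued against, since the cortical excitatory list differed by −0.063 and the upper-layer list by 0.037. Whether the excitatory genes are particular to cortex was not checked. A candidate explanation is RNA from adjoining striatal tissue in replicate 2: a second list of 12 striatal genes, sharing no member with the first, had a median of 0.87 with Isl1 (0 and 81 counts) set at its bound or not, and 12 of 12 members were higher (12 adjusted over the list alone), among the most abundant Gng7 at 42.6 and 75.1 TPM and Foxp1 at 43.8 and 49.8, although cortex expressed 10 of the 12 at 1 TPM or more in both libraries. RNA from adjoining hippocampal tissue in replicate 1 stayed open. A second list of 6 genes had a median of −0.16, close to the random range of −0.11 to 0.12. Of its members 5 were lower past the threshold and 1 higher (6 adjusted over the list alone). By the limit set in advance this median counted against the explanation, and only the margin chosen afterwards left it undecided. The most abundant gene of that list, Ociad2, stood at 42.9 and 33.5 TPM, and 5 of the 6 reached 1 TPM in both libraries. The labels call the tissue cortical plate and give no second group, so no biological explanation was tested.

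Y-linked genes had at most 1 count although the labels give pooled littermates of both sexes. A reference without the Y chromosome was argued against, since Gm37158 on that chromosome had 23 counts in each library. This rests mainly on that gene: of 1569 genes annotated there, 5 had counts in replicate 1 and 2 in replicate 2. In all they held 41.1 and 35.4 counts. Whether the reads of Gm37158 also fit other places was not checked. Too little depth was argued against, since the highest limit was 0.110% of the X-linked partner. Reads shared with the X-linked partners were argued against because at least 99.5% of the read-length windows of each Y-linked gene occurred in that gene alone. Xist stood at 99.7 TPM in replicate 1 and 79.5 in replicate 2. A pool with little or no male tissue may be the source, which stays open and was not tested.

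Several non-coding RNAs, most of them without a long poly(A) tail, were higher in replicate 2: Rpph1 by 5.75-fold (5.50 to 6.02), Rn7s1 by 3.98-fold (3.92 to 4.03), Rmrp by 3.46-fold (3.26 to 3.68), Rn7s2 by 3.41-fold (3.37 to 3.46), Gm42418, annotated as a long non-coding RNA, by 2.26-fold (2.25 to 2.26), Rn7sk by 1.89-fold (1.87 to 1.91) and the mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 by 1.44-fold (1.43 to 1.44) and 1.40-fold (1.39 to 1.41). The deposited credible bounds of TPM were far wider for Rn7s1, at 1721 to 5044 in replicate 1 and 6317 to 19522 in replicate 2. For Rn7s2 they were 2071 to 5397 and 5642 to 18823, so the size of these 2 ratios is uncertain. A preference for short transcripts was argued against as the whole cause by protein-coding genes of 200 to 350 nt. Their median log2 was −0.00884 (SD 0.96, 12 genes tested), against 1.79 for the 5 RNAs of that length above. Of the 12, 2 were higher and 1 lower past the threshold (3 adjusted over the list alone). With the margin used for the other lists, from random lists (−0.28 to 0.28), that test would not decide. The 3 longer RNAs rose too (median 0.52, SD 0.39), but they were named for being higher, so their rise could not count as a test. Less complete selection of polyadenylated RNA in replicate 2 may be the source. Replication-dependent histone genes, whose RNAs typically lack the tail, had a median log2 of 0.45, above the random range of −0.11 to 0.14. Of 48, 17 were higher and 1 lower past the threshold (20 called adjusted over the list alone). Whether each member lacks the tail was not checked, so the list may mix both kinds. Less complete selection stays open because the limit set in advance for that list was higher. Mitotic genes, whose cells make such histones, were higher as well (0.82). No biological explanation was tested.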
